A study of Arabidopsis thaliana with 8 samples.

How the data were processed

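Gene expression was measured on 8 single-channel Affymetrix arrays with biotin-labelled RNA from Arabidopsis thaliana. Samples were wild-type (WT) roots, WT protoplasts, hira roots and hira protoplasts, with 2 arrays in each of the 4 groups. Protoplasts are plant cells freed from their walls by enzymes. Groups and replicate numbers were taken from the sample titles. The labels list enzyme digestion as the treatment of the root samples as well, so whether the root samples met the enzymes is open. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

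The deposited values are treated as log2 values made with GCRMA, a background correction and normalization for Affymetrix probe sets, per the submitters' processing notes, which give no version. The log base is not given in the sources used here. The widest range of a probe set over the 8 arrays was 11.23, above the 11.09 that a natural log of a 16-bit signal can span, and log2 is the scale GCRMA gives. Every probe set had a median of 0 over the 8 arrays within rounding. The deposited values are therefore centred per probe set: differences between arrays are kept, the expression level of a gene is not, and signal over background cannot be read from them. The number of arrays limits the precision, and no column of per-sample values was left unused.

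The 64 control probe sets were set aside and used only as controls, which left 22746 probe sets for testing. No low-value filter was applied, since centred values keep no level. The platform annotation used here gave 1 gene for 13513 probe sets, several genes for 503 and listed no gene for 8794. Names were updated by gene ID through a RefSeq gene table, which matched 13436 of the single-gene probe sets. A symbol other than the locus code was found for 1580 probe sets of 1557 genes. Genes are named only from single-gene probe sets, and no coordinates are given because no genome build is named. A gene with several probe sets was to be represented by that with the highest mean over the 8 arrays. With centred values this mean carries no level, so for 146 genes the choice is arbitrary.

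The 4 group means were fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 4 residual degrees of freedom per probe set and an estimated prior of 0.742 degrees of freedom. The 5 contrasts were protoplast against root in WT, protoplast against root in hira, hira against WT in roots, hira against WT in protoplasts, and the difference between the genotypes' responses. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets tested. Standard errors (SE) are those of the fit. Response size was compared as the median of the hira minus the WT response, signed by the mean response, over probe sets called in the mean response with an absolute log2 change of at least 1. It was tested by exact permutation of the genotype labels within roots and within protoplasts.

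Before the data were examined, 22 gene lists with 352 loci, the comparisons, the alternatives and the rule for named genes were fixed. Only 40 of these loci have a single-gene probe set in the annotation used, and 7 lists had at least 3 measured genes. These 7 were tested in each comparison with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The rule named the 6 genes with the largest rise and the 6 with the largest fall in each protoplast against root comparison, and 8 per direction in the others, among called genes with a symbol whose arrays did not overlap between the groups. It also named all measured members of the HIRA complex list, and for every list up to 2 called members per direction in WT and up to 2 in the difference. Because coverage was thin, 33 gene families were formed from gene symbols after values had been seen and tested in the 5 comparisons, 165 tests in all. Of these, 30 passed with the preset correlation and 0 with an estimated correlation.

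The fit was tested on simulated data in which 200 of the 22746 probe sets, drawn from outside the 25% with the smallest residual spread, were changed. In the simulated hira protoplast against root comparison, 22% of log2 changes of 1, 40% of changes of 2 and 68% of changes of 4 were recovered, with 6 false calls. In hira against WT protoplasts the shares were 18%, 38% and 70%, with 5 false calls. In the simulated difference they were 8%, 26% and 49%, with 2 false calls. Camera called 5 of 5 shifted sets and 0 of 15 unshifted sets. Simulated noise was independent between probe sets and only 1 group was shifted each time, so these rates need not hold for the data. The noise of a probe set also had the same SD in every group. In the data the SD of replicate differences was 0.736 in WT roots and 0.309 in hira protoplasts. The false calls counted here therefore say nothing about unequal spread between groups.

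The alternatives chosen before the data were examined were quantile normalization, median centring of each array, eBayes with trend and robust, fits of the compared groups alone, a replicate block, an absolute log2 change of at least 1, 1 probe set per gene, and leaving out each of the 8 arrays. After the data were seen, a filter at an SD of at least 0.2 over the arrays and a centring on the 25% of probe sets with the smallest SD were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.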

Results

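Transcript levels were compared between Arabidopsis roots and protoplasts made from roots by enzyme digestion, in WT plants and in a hira background. HIRA is a histone chaperone that deposits the H3.3 variant outside DNA replication. The series asks how hira affects the dedifferentiation that protoplast formation brings about. Each of the 4 groups had 2 arrays, and values are GCRMA log2 values centred on each probe set's median, so only differences between arrays can be read.

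HIRA itself has no probe set named in the annotation used, so the genotype labels could not be checked by its transcript. Its partners UBN1, UBN2 and CABIN1 are likewise not analysed here. The first principal component held 61.3% of the variance and separated protoplasts from roots. Mean scores on it were -116.8 ± 4.31 in hira roots, -64.2 ± 14.8 in WT roots, 75.6 ± 3.42 in hira protoplasts and 105.4 ± 18.5 in WT protoplasts (SD, n = 2). Replicates correlated across probe sets at r = 0.575 in WT roots, 0.739 in WT protoplasts, 0.808 in hira roots and 0.878 in hira protoplasts, where probe sets are not independent.

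**Figure D1:**
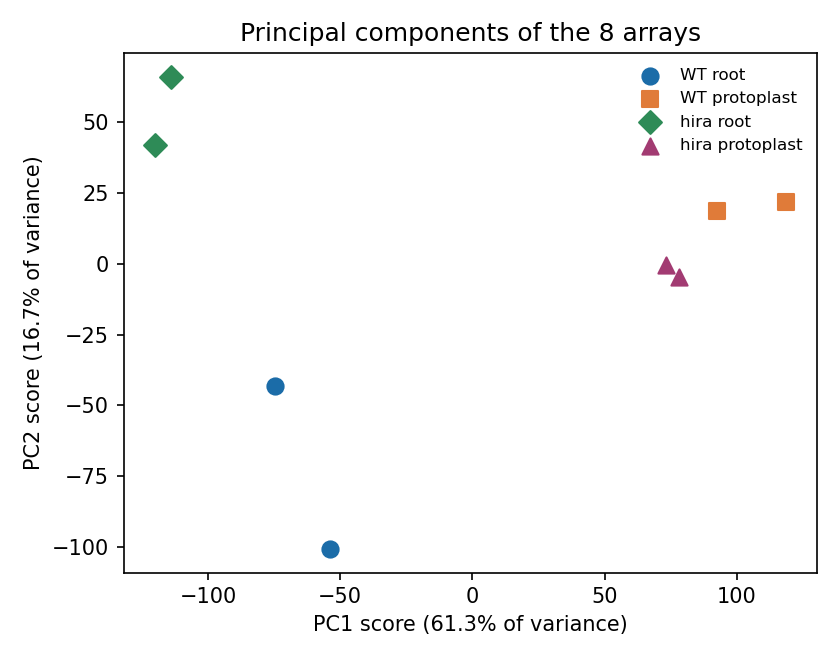
Scores of the 8 arrays on the first and second principal components (axes in score units, with the percent of variance held), with a colour and marker for each group of 2 arrays. Protoplast arrays lie at positive and root arrays at negative scores of the first component, and hira roots lie farther from the protoplasts than WT roots.

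RNA controls differed between the groups. The 5′ minus 3′ gap of the GAPDH control was -2.22 ± 0.04 in WT roots, against 0.62 ± 0.19 in WT protoplasts, 0.04 ± 0.12 in hira roots and -0.09 ± 0.01 in hira protoplasts (SD, n = 2). The actin control gave -1.81 ± 0.47, 1.52 ± 0.32, -0.25 ± 0.13 and 0.26 ± 0.06 in the same order. The WT arrays thus held the lowest and highest gaps, and every comparison with WT roots or WT protoplasts carries this difference beside its gene values.

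**Figure D2:**
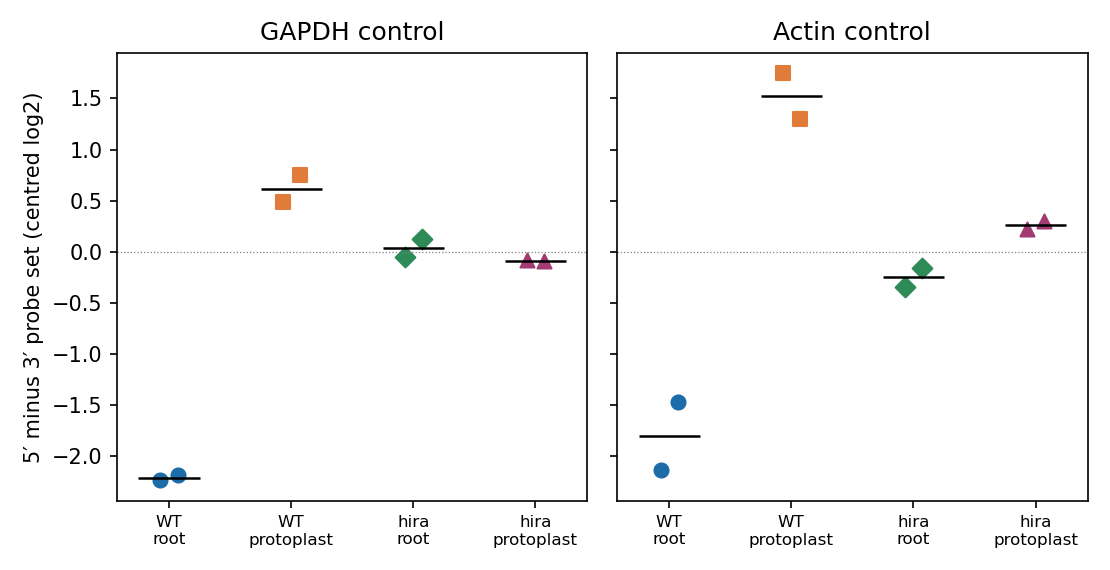
Difference between the 5′ and the 3′ probe set of the GAPDH and actin controls (centred log2, vertical axis) for each array by group, where points are arrays and lines are group means. The WT root arrays average -2.22 for GAPDH and -1.81 for actin, below the other 3 groups.

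Protoplasts of WT plants showed a broad change against WT roots. Here and below, the largest changes are those among the 1557 genes with a symbol, not among all 22746 probe sets tested. Among the largest rises, LEA4-5, a late embryogenesis abundant protein, rose by 7.43 (log2, SE 0.43), JRG21, a jasmonate-induced oxygenase, by 6.85 (SE 0.19), IAA30, an auxin response repressor, by 6.05 (SE 0.66) and COR47, a dehydrin, by 4.80 (SE 0.52). The protease gene CP1 rose by 5.46 and SIS by 5.38. The largest falls were in FACT, an acyltransferase of root suberin waxes and not the chaperone of that name, at -7.60 (SE 0.22), the plantacyanin ARPN at -6.66, the defensin gene PDF2.5 at -6.52 (SE 0.05) and the thaumatin-like ATLP-1 at -6.17. The chitinase gene ChiC changed by -5.64 and the signalling peptide gene RALFL34 by -5.55. Adjusted p for these 12 genes lay between 2.34e-05 for PDF2.5 and 0.0172 for CP1 (limma). The values of PDF2.5 and ATLP-1 were nearly equal between the WT protoplast arrays, with SDs of 0.003 and 0. Whether such values lie at the signal floor cannot be read from centred values. If they do, the falls are lower bounds and a small SE is no measure of their precision.

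Cell division genes fell in WT protoplasts. All 3 measured members of the cell cycle and DNA replication list fell, also adjusted over the list alone, including the replication helicase subunit PRL (MCM7) at -3.56 (SE 0.22) and the mitotic kinase AUR1 at -3.47 (SE 0.09). For PRL and AUR1 the SD in WT protoplasts was 0.001 and 0.002, so the same limit on SE and size applies. The list passed camera (adjusted p = 0.000314), with adjusted p = 0.102 with an estimated correlation. That correlation was -0.129, so correlation between these genes does not account for the larger value. Among histone chaperones, ASF1B changed by -1.67 (SE 0.30) and the H3.3-associated remodeller ATRX by -1.03 (SE 0.14), while SGA2 (ASF1A) rose by 1.44 (SE 0.12), and adjusted over the list alone the counts were likewise 1 rise and 2 falls. The 5 measured callus and pluripotency factors gave 1 rise, LBD16 at 2.28 (SE 0.50), and 1 fall, BBM at -2.34 (SE 0.38), with the same counts adjusted over the list alone. BBM is also the only measured member of the root cap and stem cell niche list.

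The remaining lists held few measured genes. Of the 2 abscisic acid and water deficit genes 1, COR47, rose, also adjusted over the list alone. In the cell wall list 1 of 4 members fell, XTH18 at -3.53 (SE 0.45), and in the stele list its single member LHW fell by 1.84 (SE 0.41). The ethylene response factor AT5G61890 (ERF114) rose by 2.11 (SE 0.33), the glutathione transferase GSTU25 rose by 0.82 (SE 0.14), and the ribosomal protein gene AT5G02870 (RPL4D) changed by -1.68 (SE 0.21). The list-alone counts were 1 fall in the cell wall list, 1 fall in the stele list, 1 rise in the ethylene list, 2 rises of 2 heat and oxidative stress genes and 2 falls of 2 ribosomal genes, adjusted over the list alone. No member passed among 2 root hair, 3 endodermis and cortex, 3 defence, 4 auxin, 2 hypoxia and 2 cytokinin genes, or for RCA, the single green-tissue gene. In total 5817 probe sets were called in WT, 2659 higher and 3158 lower, of which 4652 changed at least 2-fold. The count was 2331 with the WT arrays alone, 3747 without WT protoplast replicate 1 and 3877 without either hira protoplast array, and 12 of the 24 named calls held under every alternative.

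In hira protoplasts against hira roots JRG21 rose by 8.22 (SE 0.19) and IAA30 by 7.78 (SE 0.66), as in WT among the largest rises. GH3.3, an auxin-conjugating enzyme, rose by 8.82 (SE 1.24), the alkenal reductase gene AER by 7.66 (SE 0.54), UGT76E12 by 6.25 (SE 0.87) and the stress zinc finger gene STZ (ZAT10) by 6.05 (SE 0.51). The largest falls were PDF2.5 at -7.12 (SE 0.05), FACT at -7.09 (SE 0.22), ATLP-1 at -5.96 (SE 0.38), the SKU5-like gene sks15 at -5.92 (SE 0.51), the transcription factor gene BZIP61 at -5.59 (SE 1.1) and RALFL24 at -5.54 (SE 0.16). Adjusted p ran from 1.16e-05 for PDF2.5 to 0.0255 for BZIP61 (limma). The values of PDF2.5, FACT and ATLP-1 were nearly equal between the hira protoplast arrays, with SDs of 0.002, 0.001 and 0.002. The limit given for nearly equal values in WT protoplasts applies to these falls too.

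The 3 cell cycle genes fell in hira protoplasts too (camera adjusted p = 0.00311), with adjusted p = 0.167 with an estimated correlation. In the auxin list 1 of 4 members, GH3.3, rose over all probe sets and 4 of 4 adjusted over the list alone (camera adjusted p = 0.00782), with adjusted p = 0.175 with an estimated correlation. In the endodermis and cortex list 2 of 3 members fell, 3 adjusted over the list alone. 1 of the 2 falls, AT1G62500 (CO2), was only -0.27, with centred values from -0.121 to 0.157 over all arrays. The list passed camera (adjusted p = 0.0416), with adjusted p = 0.175 with an estimated correlation. It was not tested with the SD filter, which left fewer than 3 of its genes. That call was lost without WT root replicate 1 or 2 (adjusted p = 0.0543), hira root replicate 1 (0.0632) or 2 (0.107), and hira protoplast replicate 1 (0.0655), and with the hira arrays alone (0.0579). Of the chaperones, ATRX rose by 1.09 (SE 0.14), SGA2 rose by 0.68 (SE 0.12) and ASF1B fell by 1.56 (SE 0.30), with the same counts adjusted over the list alone. AT5G61890 rose by 6.82, 2 of 4 cell wall genes and 1 of 2 root hair genes fell, and 1 of 5 callus and pluripotency factors rose; adjusted over the list alone the counts were 1, 2, 2 and 1. Of 3 defence genes 1 rose and 1 fell, 2 and 1 adjusted over the list alone. The fall was PDF1.2 at -0.30, with centred values from -0.18 to 0.189 over all arrays. Of 2 heat and oxidative stress genes 1 rose and 1 fell, also adjusted over the list alone, with GSTU25 at -1.52. In total 5505 probe sets were called, 2726 higher and 2779 lower, and 4214 changed at least 2-fold. The count was 1872 without hira protoplast replicate 2 and 2150 without hira protoplast replicate 1, and 9 of the 15 named calls held under every alternative.

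The responses of the genotypes overlapped. Of 3012 probe sets called in both, 1387 were higher in both, against 319 for independent lists, 1505 were lower in both, against 386, and 120 went in opposite directions. Both tests use the same spread estimate for a probe set, so the lists of calls are not independent even where responses are unrelated. The excess over independent lists is therefore partly built in. A shared spread alone would not favour the same direction over opposite ones. The responses correlated at r = 0.625 across probe sets, which are not independent replicates, and share no arrays. Over 5291 responding probe sets the hira minus WT response, signed by the mean response, had a median of -0.04 log2, with an SD of 0.14 over 16 sets of single arrays. This pooled opposite values, 0.12 over the probe sets that rose and -0.21 over those that fell. The count called alike in both genotypes, 2892, was 1277 and 1145 without hira protoplast replicates 1 and 2. An exact two-sided permutation test of the response size gave p = 0.944, where 17 of 18 splits were as large and the smallest possible p is 0.0556. The median was -0.25 without WT protoplast replicate 2, and 0.32 over probe sets with a mean response of at least 2.

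**Figure D3:**
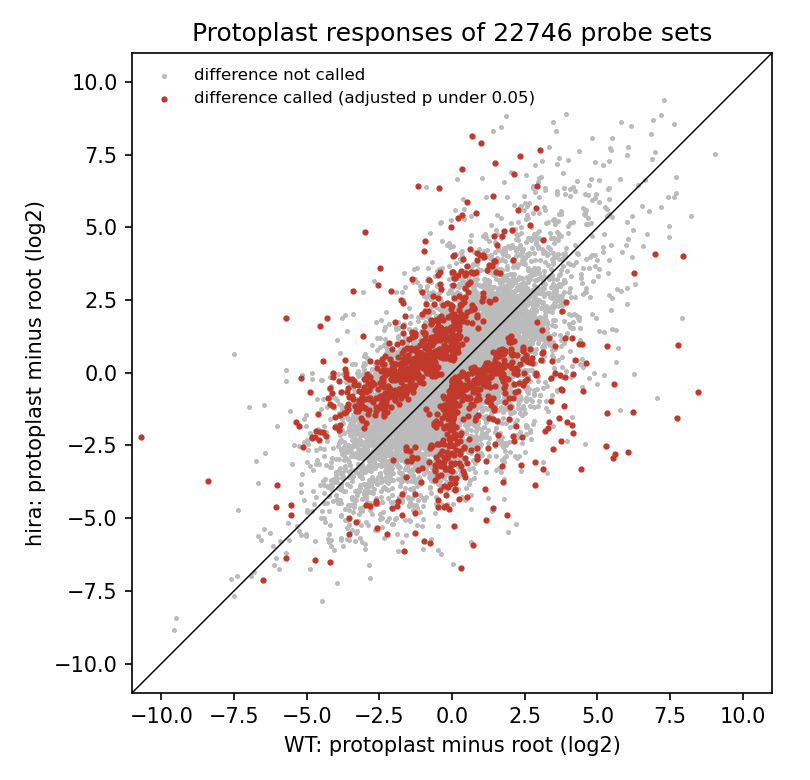
Protoplast minus root change (log2) of each of 22746 probe sets in WT (horizontal axis) and hira (vertical axis), with the line of equal change. The 1108 probe sets whose responses differed between the genotypes are in red, and the responses correlate at r = 0.625.

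Roots of hira plants differed from WT roots in both directions. sks15 was higher by 5.83 (SE 0.51), the linker histone gene HIS1-3 by 4.65 (SE 0.66), the xylan synthesis gene IRX15-L by 3.57 (SE 0.47), the transporter gene OCT1 by 3.54 (SE 0.30), the ERF-type factor gene tny by 3.22 (SE 0.31), hemb2 by 3.09, ATGSTF13 by 3.02 and sks16 by 2.97. Lower in hira roots were GH3.3 at -6.52 (SE 1.24), AER at -4.45 (SE 0.54), the calmodulin-like gene CML37 at -3.95 (SE 0.39), the glutaredoxin gene GRX480 at -3.91, EXO at -3.67, the protease gene NANA at -3.06, ARPN at -3.02 and STZ at -2.997. Adjusted p lay between 0.00669 for hemb2 and 0.0459 for GH3.3 (limma). ATRX was lower in hira roots by -1.88 (SE 0.14, adjusted p = 0.00863), while SGA2 was at 0.14 and ASF1B at 1.22 with adjusted p = 0.599 and 0.0757, and adjusted over the list alone 1 of the 3 was higher and 1 lower.

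No fixed list passed camera in roots, although 1 did without WT root replicate 2 or without either hira protoplast array, and fry called 3. In the cell cycle list 1 of 3 genes was higher in hira roots, 2 adjusted over the list alone. In the auxin list 1 of 4 was lower, 1 adjusted over the list alone, and AT5G61890 was lower at -2.65. COR47 was higher by 2.67 and AT1G62500 by 0.16, while XTH18 was lower at -2.75. Adjusted over the list alone, 2 of 2 root hair genes were higher and BBM was lower. In total 2090 probe sets were called, 1117 higher and 973 lower in hira, of which 1434 changed at least 2-fold. With the 4 root arrays alone limma called 0 probe sets, although 4548 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0712. Every call in roots thus rests on the spread shared with the protoplast arrays. The fit of the root arrays alone is among the alternatives, so no call in roots could hold under every alternative. The named calls of ATRX, CML37, OCT1, hemb2, sks15 and tny were lost under no other alternative. The SD of replicate differences was 0.736 in WT roots, 0.615 in hira roots, 0.612 in WT protoplasts and 0.309 in hira protoplasts. The shared spread may therefore be too small for comparisons with WT roots. It may also be too small for some genes raised in hira roots. OCT1 had an SD of 0.658 in hira roots against 0 to 0.07 in the other groups, and ATGSTF13 1.158 against 0.004 to 0.046. For sks15, tny and sks16 the SD was not largest in hira roots. The count was 1332 after quantile normalization, 495 without either hira protoplast array, 1082 without WT root replicate 2 and 1149 without hira root replicate 2, and 0 of the 17 named calls held under every alternative.

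Protoplasts of hira plants differed from WT protoplasts in both directions. AMY1, an alpha-amylase gene, was higher by 3.97 (SE 0.04), the pentatricopeptide gene PPR596 by 3.47 (SE 0.25), the defensin-like LCR69 by 3.21 (SE 0.24), SETH6 by 3.17 (SE 0.22), the plastid chaperonin gene Cpn60beta2 by 2.96 (SE 0.25), the subtilase gene SBT3.3 by 2.80 (SE 0.20), the receptor kinase gene MOL1 by 2.79 (SE 0.11) and bZIP58 by 2.71 (SE 0.38). Lower were AtLEA4-1 at -3.53 (SE 0.12), the pectin methylesterase gene PMEPCRF at -2.94, AAH at -2.08, the xylan acetylation gene TBL34 at -1.81, DRT100 at -1.76, GSTU25 at -1.68, the xylan synthesis gene IRX15 at -1.53 and SETH5 at -1.37. Adjusted p ran from 6.9e-05 for AMY1 to 0.0361 for DRT100 (limma).

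Of the 3 cell cycle genes, 2 were higher in hira protoplasts, also adjusted over the list alone (camera adjusted p = 0.0078), with adjusted p = 0.211 with an estimated correlation, and the list no longer passed after quantile normalization (adjusted p = 0.462) or with probe sets of an SD of at least 0.2 only (adjusted p = 0.0709). AT5G61890 was higher by 2.06, and 1 of 2 ribosomal genes was higher, 2 adjusted over the list alone. None of the 3 chaperones passed, with ATRX at 0.24, SGA2 at -0.62 and ASF1B at 1.32, while adjusted over the list alone 1 was higher and 1 lower. In total 1885 probe sets were called, 1149 higher and 736 lower, and of the 1051 with at least 2-fold changes 830 were higher and 221 lower. The split was 1175 higher and 468 lower after centring on the least variable probe sets, and the eBayes fit with trend and robust called 4773, of which 3090 were lower. The count was 695 with the protoplast arrays alone, 139 and 207 without hira protoplast replicates 1 and 2, 855 and 905 without WT protoplast replicates 1 and 2, and 893 without either hira root array, and 3 of the 16 named calls held under every alternative: AMY1, AtLEA4-1 and MOL1.

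The responses to protoplast formation themselves differed between the genotypes for 1108 probe sets, 593 with a higher and 515 with a lower response in hira. SBT3.3 had the largest named gain, 5.38 (SE 0.28, adjusted p = 0.00579), and AMY1 differed by 3.97 (SE 0.06, adjusted p = 0.000355), with values near 0 in the other 3 groups. The SD of AMY1 was 0.071 in hira protoplasts and 0.002 to 0.013 elsewhere, so the shared spread lies below that of the raised group. AtLEA4-1 had an SD of 0.263 in WT protoplasts, against 0 to 0.022 in the other groups. OCT1 had an SD of 0.658 in hira roots, against 0 to 0.07 in the other groups. Further higher responses were in the mitochondrial gene cox2 at 5.18, CML37 at 5.14, AER at 4.64, Hsp70-2 at 4.09, TRM19 at 3.84 and the photosystem gene psbA at 3.5 (limma). For each of these the genotypes differed by limma in roots, where hira was lower, and did not pass in protoplasts. Hsp70-2 was not induced in hira, as its response was -4.10 in WT and -0.02 in hira. Lower responses in hira were those of sks15 at -6.62 (SE 0.72), IRX15-L at -5.0, tny at -4.08, PMEPCRF at -4.03, DRT100 at -3.88, TBL34 at -3.72 (SE 0.19), OCT1 at -3.58 and AtLEA4-1 at -3.54 (SE 0.18). Of these, sks15, IRX15-L, tny and OCT1 differed by limma in roots, where hira was higher, and did not pass in protoplasts. ATRX differed by 2.12 (SE 0.20, adjusted p = 0.0203), as it fell in WT and rose in hira, whereas SGA2 and ASF1B did not pass, at -0.76 and 0.11, and adjusted over the list alone 1 response was higher and 1 lower. Of other list members, AT5G61890 differed by 4.71 (SE 0.46), GSTU25 by -2.34 (SE 0.20) and the cortex marker AT1G62500 (CO2) by -0.27 (SE 0.04).

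**Figure D4:**
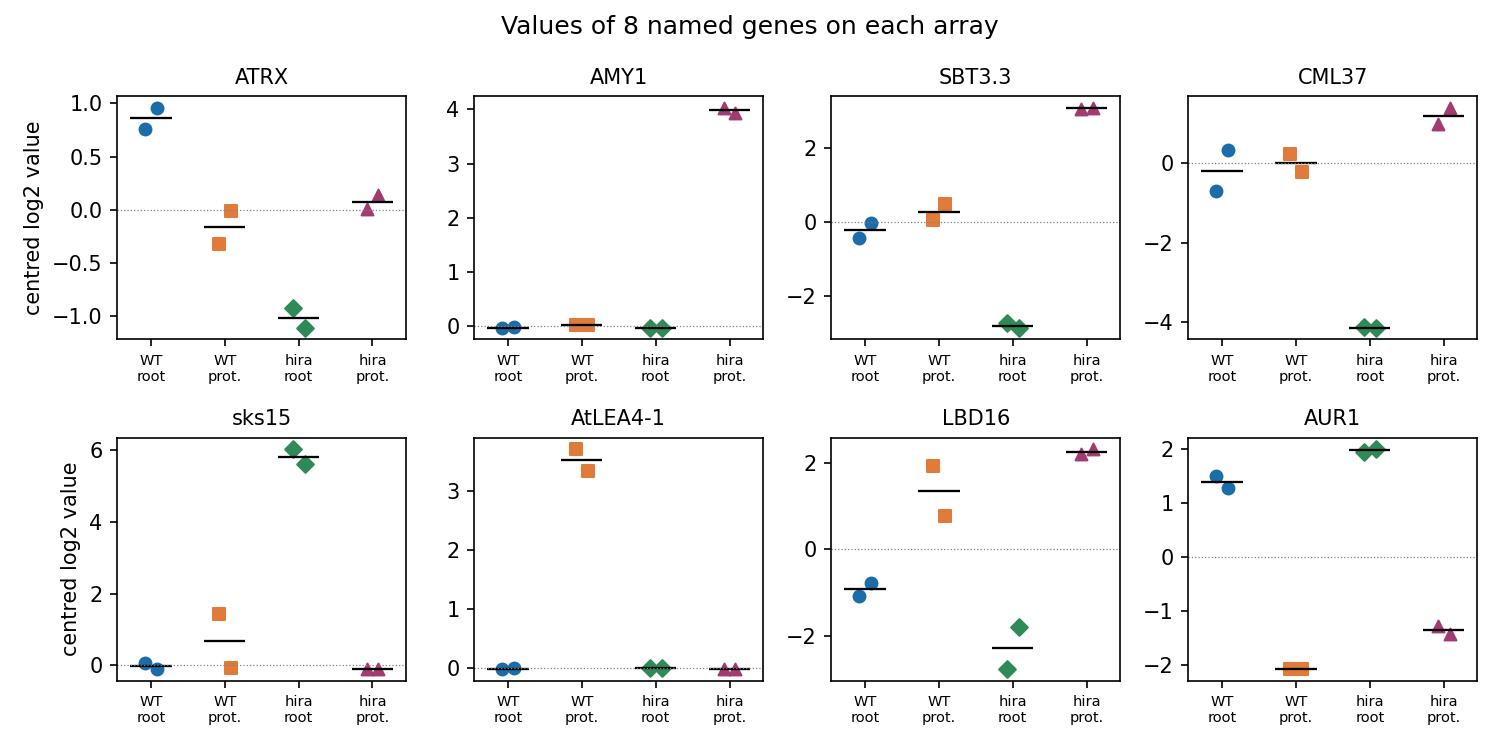
Centred log2 values (vertical axis) of 8 named genes on each array by group, where points are arrays and lines are group means (prot., protoplast). AMY1 is raised in hira protoplasts only, at a mean of 3.98, and AtLEA4-1 in WT protoplasts only, at a mean of 3.52.

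Among the 1108 probe sets, 388 were called in the hira response only, 362 in the WT response only, 115 in opposite directions, 98 in the same direction with a larger change in hira and 145 with a larger change in WT. The genotypes differed in roots only for 570 of them, in protoplasts only for 366, in both for 133 and in neither for 39. No fixed list passed camera for the difference, although 1 did without WT root replicate 1, without WT protoplast replicate 1 and without either hira protoplast array, and fry called 0. The count was 610 with trend and robust, 142 and 168 without hira protoplast replicates 2 and 1, 573 and 607 without WT protoplast replicates 1 and 2, and 2185 without WT root replicate 1. Lower responses outnumbered higher ones without hira root replicate 1 (595 higher, 820 lower) or 2 (287 and 478), without WT protoplast replicate 1 (275 and 298) or 2 (294 and 313), and with 1 probe set per gene (239 and 257). The replicate block likewise gave more lower responses, 163, than higher ones, 139. Of the 20 named differences, 4 held under every alternative: AMY1, AtLEA4-1, SBT3.3 and TBL34. Those of ATRX, AT5G61890, DRT100 and GSTU25 were lost without either hira protoplast array and under no other alternative, and that of AER was lost in 13 of 16.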

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

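The tests weighed here on the roots and the plastid transcripts were chosen after the results had been seen.

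The protoplast response differed between the genotypes, by the test of the difference itself, for 20 named genes. The hira response was higher by 5.38 for SBT3.3, 5.18 for cox2, 5.14 for CML37, 4.71 for AT5G61890, 4.64 for AER, 4.09 for Hsp70-2, 3.97 for AMY1, 3.84 for TRM19, 3.5 for psbA and 2.12 for ATRX. It was lower for sks15 at -6.62, IRX15-L at -5.0, tny at -4.08, PMEPCRF at -4.03, DRT100 at -3.88, TBL34 at -3.72, OCT1 at -3.58, AtLEA4-1 at -3.54, GSTU25 at -2.34 and AT1G62500 at -0.27.

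Control probe sets, which the comparisons do not use, showed signals that follow the groups. The 5′ minus 3′ gap in WT roots was -2.22 for GAPDH and -1.81 for actin. The spiked-in bioB control was at -4.12 in hira protoplasts, against 0.98 in WT roots, 0.17 in WT protoplasts and -0.22 in hira roots. The fall was not shared by the bioC control, at -0.30 in hira protoplasts, or the poly-A controls, at 0.20.

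WT roots lay nearer to the protoplasts than hira roots did, with first component scores of -64.2 and -116.8. The displacement of WT roots from a hira root array correlated across probe sets at 0.505 and 0.421 with the hira response taken from the other hira root array, which describes the same pattern and separates no explanation. The mirror test on the WT side gave 0.08 and -0.104, where a shift of the WT root arrays of their own, such as 3′ bias, adds a positive part and a partial protoplast response in WT roots a negative part. Values near 0 may come from a shift of the hira root arrays alone or from both of these parts together. 3′ bias and a partial response in WT roots therefore cannot be told apart here, and a shift of hira roots, by genotype or preparation, stays open as well.

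Of 69 plastid-encoded transcripts 11 were called higher and 0 lower in hira than in WT protoplasts by limma and 58 did not pass, with a median of 0.82, or 0.75 after quantile normalization (camera adjusted p = 3.45e-09), but adjusted p = 0.837 with an estimated correlation. Their median change from roots to protoplasts was -0.669 in WT and 0.098 in hira, so the contrast lies largely in a fall in WT. More chloroplast-like plastids would raise nuclear photosynthesis genes. All 15 of these had a median of -0.319 with 0 above 0.5, and 0 genes passed limma. The median was -0.477 to -0.281 over pairs of single arrays, which reuse the same arrays and are no independent support. The 13 with an SD of at least 0.2 had a median of -0.566. This argues against such a rise for these genes in these arrays only. A difference in the capture of organelle RNA between preparations could shift mitochondrial transcripts too. Their median was 0.664 over 14 genes, without passing the list test (camera adjusted p = 0.171), so capture and genotype cannot be told apart here.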

How the results depend on the processing

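The SD filter and the centring on the least variable probe sets were chosen after seeing the data. No low-value filter was applied to centred values, so the alternative without a filter equals the reported fit, and the higher filter and the pseudocount could not be run. HIRA transcript level has no value under any setting. No named gene reversed. The named calls in roots could not hold under every alternative, since the fit of the root arrays alone gave no calls. Of 92 named calls 28 held under every alternative, and 40 under every omission of an array. Signal over background is not kept in centred values, so what it limits cannot be given. Where an omission leaves a group with 1 array, that array is assumed to vary like the other groups; the cause of the changes below was not tested unless stated.

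Quantile normalization gave 1332 calls in roots and 0 called lists in hira against WT protoplasts, where the SD filter also gave 0. Trend and robust gave 4773 calls in hira against WT protoplasts and 610 for the difference. The compared groups alone, with fewer arrays, gave 2331 calls in WT against 5281 in hira, 0 in roots and 695 in hira against WT protoplasts. Requiring an absolute log2 change of at least 1 gave 1051 in hira against WT protoplasts. With 1 probe set per gene, which tests fewer probe sets, the counts were 2961 in WT, 2887 in hira, 1034 in roots, 496 for the difference and 1435 called alike in both genotypes. An estimated correlation left 0 lists in WT, hira and hira against WT protoplasts, and fry called 2 in WT, 5 in hira and 3 in roots. The response size was 0.32 at a mean response of at least 2.

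Replicate numbers did not pair the samples: same-numbered deviations correlated between groups at -0.10 to 0.05. With the replicate block the counts were 1030 in roots with 1 called list, 789 in hira against WT protoplasts and 302 for the difference (139 higher, 163 lower), the endodermis and cortex list in hira was at adjusted p = 0.0648, and no other count moved beyond 1.5 times.

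Leaving out each array in turn gave 3747 to 5377 calls in WT, 1872 to 5628 in hira, 495 to 3085 in roots, 139 to 1559 in hira against WT protoplasts and 142 to 2185 for the difference. The lowest counts came without WT protoplast replicate 1 in WT, without hira protoplast replicate 2 in hira and for the difference, without either hira protoplast array in roots, and without hira protoplast replicate 1 in hira against WT protoplasts. Calls shared in direction by both genotypes ranged from 1145 to 2767 and the response size from -0.2501 to 0.02985. Called lists ranged from 1 to 1 in WT, 2 to 3 in hira, 0 to 1 in roots, 1 to 2 in hira against WT protoplasts and 0 to 1 for the difference.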

Other observations

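Gene families below were formed after values had been seen, and none of their list tests held with an estimated correlation. The test of the pseudogenes by quantile normalization was fixed before its result was seen, and the centrings were looked at afterwards.

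Of 26 measured genes of mitosis and DNA replication, 14 fell in WT (camera adjusted p = 9.99e-07; adjusted p = 0.524 with an estimated correlation) and 13 in hira (3.74e-06; adjusted p = 0.411 with an estimated correlation), and none was called as a rise. The mitotic chromatin protein 3xHMG-box2 changed by -5.34 in WT and -5.27 in hira, topoisomerase TOPII by -4.25 and -3.95, and the cytokinesis motor KINESIN-12B by -1.80 and -2.09. The family shares AUR1, AUR2 and PRL with the cell cycle list. For the difference between the genotypes its median was near 0, at 0.0571 with centring on the least variable probe sets and -0.0917 after quantile normalization, and limma called 0 members. The 5 probe sets that the annotation assigns jointly to several H3.1 histone genes also fell in both genotypes, from -0.80 to -3.72 in WT and from -0.90 to -3.35 in hira. Of the H3.1 probe sets, 1 was higher in hira than in WT protoplasts, by 1.61 (limma adjusted p = 0.0217). None of 3 joint H3.3 probe sets passed in protoplasts against roots, while 1 of them was higher in hira roots by 1.03 and in hira protoplasts by 0.998.

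Some members of membrane traffic and wall families also passed, and none of these families passed with an estimated correlation. In WT protoplasts 7 of 12 ESCRT genes of endosomal sorting rose and 1 fell, VPS2.2 at -4.41 (camera adjusted p = 0.0487; adjusted p = 0.621 with an estimated correlation). Of 10 autophagy genes, 2 rose in WT and 3 in hira, with ATG8H at 3.53 and 2.995 (camera adjusted p = 0.0332 and 0.0123; adjusted p = 0.882 and 0.597 with an estimated correlation). In hira protoplasts 5 of 7 tubulin genes fell and 1, TUA1, rose by 3.35 (camera adjusted p = 0.0475; adjusted p = 0.469 with an estimated correlation), and 8 of 22 wall acetylation genes of the TBL family fell, TBL36 at -4.89 (camera adjusted p = 0.0118; adjusted p = 0.411 with an estimated correlation). The TBL median was similar in both genotypes, at -0.275 in hira and -0.231 in WT.

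Of 989 pseudogenes, 121 were called lower and 4 higher in hira than in WT protoplasts and 864 did not pass, with a median of -0.10 against -0.05 over all probe sets, and the 6830 probe sets with an SD under 0.2 had 276 falls and 7 rises. A shift of the signal floor between arrays is a candidate explanation. After quantile normalization 130 falls were called, 98 of them shared with the 121, and the probe sets with an SD under 0.2 had 285 falls. Centred values keep no signal level, so quantile normalization cannot align the signal floor of the arrays. The rule fixed before the result took most falls staying called as evidence against a floor shift, and these counts met it. Because centred values hold no floor to align, the test cannot decide, and nothing is concluded from it. The pseudogene median shrank to -0.0387 after quantile normalization. Median centring left 85 of the 121 falls and centring on the least variable probe sets 68, at medians of -0.0478 and -0.0378. A shift may thus carry much of the pattern, but both centrings remove a shift common to many probe sets by construction, whatever its cause. Whether genotype carries the rest was not tested apart from preparation.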
